A study of Drosophila melanogaster with 2 samples.

How the data were processed

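Poly(A)-selected RNA from pooled Drosophila melanogaster embryos collected from 0 to 16 h after egg laying was sequenced as 1 library per genotype, and 2 libraries were analysed. In the first, a GAL4 driver line had been crossed to a line carrying a transgene that makes RNA interference against Lim3. In the second, the same driver had been crossed to a line with a transgene at the same landing site and no RNA interference construct. Groups were taken from the sample labels. Because the targeted gene was higher in the library labelled knockdown than in the control library, that name is used for it throughout.

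The deposited values are FPKM (fragments per kilobase of transcript and 1000000 mapped fragments), a single value per annotated transcript and library, per the file headers. The tools the authors used were TopHat, a spliced-read aligner, and Cuffdiff, which estimates transcript abundance, per the submitters' processing notes. The settings, the strand handling, the genome build and the annotation release are not given in the sources used here. Chromosome names and coordinates in the files are those of Drosophila Release 5, and coordinates of genes below are given as the files hold them unless another release is named. For some genes the files give the span of a bundle of overlapping genes rather than the gene's own span, and such spans are not printed. Libraries were made with a directional kit from fragments, and molecules of 250 to 400 bp were cut from a gel, per the labels' protocols. Because it is not known whether the counting used strand, fragments of overlapping or antisense genes were possibly shared between them. The files hold no counts, no confidence intervals and no quality status.

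From the deposited FPKM values, the transcripts of each FlyBase gene identifier were summed to a gene value. The 33887 transcripts gave 17301 genes, and 16753 of their identifiers had a name in the current gene table. A further 365 of the transcripts had no gene identifier and were left out. They held 0.0227% of the FPKM sum in the library labelled knockdown and 0.0246% in the control library. Differences are on the scale log2((knockdown + 1)/(control + 1)), which understates the difference of genes with low FPKM. The fold values printed beside them are plain ratios of FPKM. A gene was tested against the size rule if it reached 1 FPKM in at least 1 of the libraries, which left 10576 genes. The size rule was an absolute log2 difference of at least 1. The requirement of a valid estimate, and of separate confidence intervals for named genes, could not be applied because the files hold neither. An exact 0 in these files can be a failed estimate, so such genes are described as listed at 0 and get no fold.

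With 1 library per group, no difference has a replicate check, and no p-values are given. Gene lists fixed beforehand were described by the median log2 difference of their measured members and by the percentile of that median among 10000 random lists of the same size, drawn from 20 bins of mean expression. A list needed 4 measured members. A percentile under 2.5 or over 97.5 is called outside the range of random lists, and it describes these libraries only. Chance alone gives this for 5% of lists if their members vary independently, but members of a list can move together. A list's interval of the median is the order-statistic interval at 95%.

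The depth was estimated from the values. Among genes with 1 transcript of 1000 to 3000 nt, low values of FPKM times length pile up at the value of 1 fragment. That value was 29.7 in the library labelled knockdown (479 genes, bootstrap interval 27.5 to 34.1) and 47.5 in the control library (465 genes, 39.1 to 49.5). These correspond to about 33700000 and 21100000 fragments. Estimated fragments per gene gave exact binomial 95% intervals of each FPKM ratio. They rest on this estimate and cover counting error only, not the differences between embryo collections or library preparations. The estimate comes from transcripts of 1000 to 3000 nt and was not checked on shorter ones. For those, fragment numbers may be too large and intervals too narrow.

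Genes were named by a rule with 4 parts. Part 1 is the list of LIM-homeodomain and cofactor genes. Part 2 is the 12 genes with the largest and the 12 with the smallest log2 difference among genes at 5 FPKM or more in at least 1 of the libraries. Part 3 is up to 2 members per direction of each list that pass the size rule. Part 4 is the marker genes y, w, v and Ser and the host gene of the driver, en. The lists, the size rule, the naming rule and most alternatives were fixed before the data were examined. Part 2 returned only RNAs shorter than 200 nt, so the 12 genes per direction with a longest transcript of 200 nt or more were added after the values were seen, and for the lower direction also the 12 of these outside unplaced and heterochromatic scaffolds. List members named as examples beyond this rule, and genes named in the closing section, were also chosen after their values were seen.

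Alternatives were pseudocounts of 0.1 and 5, rescaling of both libraries to a sum of 1000000 over genes, centring on the median of genes at 5 FPKM or more in both libraries, no filter on low values, a filter at 5 FPKM, the mean in place of the median of a list, and random lists matched on transcript length as well. A restriction to genes of 200 nt or more and the removal of a lowess trend of the difference on transcript length (fraction 0.3) were added later. The steps were tested on simulated data made from the mean of both libraries, for genes of 200 nt or more. The only random error simulated was that of counting fragments, without differences between embryo collections or library preparations. Genes given a difference were taken at a mean of 5 FPKM or more. For this comparison, with 10309 simulated genes, 100% of genes with a 4-fold difference and 0% of those with a 1.5-fold difference passed the size rule, as did 2 of the genes with none. A muscle list with a simulated 1.23-fold shift came out at percentile 100. These results therefore give no error rate for the real libraries. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The exon map of Lim3 and the order of neighbouring genes came from the Release 6 annotation (BDGP6, Ensembl release 115), and no coordinates were converted between releases.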

Results

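The study compared embryos in which a GAL4 driver acted on an RNA interference construct against Lim3 with embryos of a control cross, by RNA sequencing of the poly(A) fraction. Lim3 encodes a LIM-homeodomain transcription factor that helps to specify motor neurons. Each group was 1 pooled collection of embryos aged 0 to 16 h and reared at 25 °C, so a pool ranged from early cleavage to late organ formation. The library labelled knockdown had 10359 genes at 1 FPKM or more and the control library 10301. Depth, estimated from the smallest values, was about 33700000 fragments (29300000 to 36400000) in the library labelled knockdown and about 21100000 (20200000 to 25600000) in the control library, a 1.60-fold difference. None of the differences below has a replicate check, and the intervals of single genes and transcripts cover counting error only.

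Lim3 (FBgn0002023) was higher, not lower, in the library labelled knockdown, which goes against that label. Its summed level was 18.5 FPKM there and 5.81 FPKM in the control library, a log2 difference of 1.51 and a 3.17-fold ratio (2.80 to 3.60). The ratio stood on about 1497 and 310 fragments. Lim3 lies on chromosome 2L from 19079256 to 19108427 in the Release 5 coordinates of the files, and the Release 6 annotation gives the same start and end. Among the 8348 genes of 200 nt or more at 5 FPKM or more, Lim3 had the 8th largest log2 difference in this direction.

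The 6 annotated Lim3 transcripts did not differ alike. The shortest, FBtr0309834 with 2284 nt, was at 13.1 FPKM in the library labelled knockdown and 2.30 FPKM in the control library, a 5.71-fold ratio (4.70 to 7.04), and accounted for 85.6% of the gene's difference. FBtr0081170, which also starts near the 3' exons, was at 2.42 and 1.26 FPKM, a 1.92-fold ratio (1.45 to 2.56). The 4 transcripts with a distal first exon summed to 2.91 FPKM in the library labelled knockdown and 2.25 FPKM in the control library, a 1.29-fold ratio (1.05 to 1.61). FBtr0329940, the most abundant of these in both libraries, was at 1.95 and 1.83 FPKM, and FBtr0309832 at 0.524 and 0.419 FPKM. The other distal transcripts were higher in the library labelled knockdown at low level, FBtr0081169 at 0.244 and 0.00158 FPKM and FBtr0309835 at 0.200 FPKM and listed at 0 in the control library. In the Release 6 annotation all 6 transcripts share 6 exons of 2159 nt in total, from 19079256 to 19081994 on 2L, and differ in the exons upstream of them. Fragments in the shared exons were divided among the transcripts by the authors' software, so the transcript values are estimates. The intervals do not cover error in that division.

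**Figure D1:**
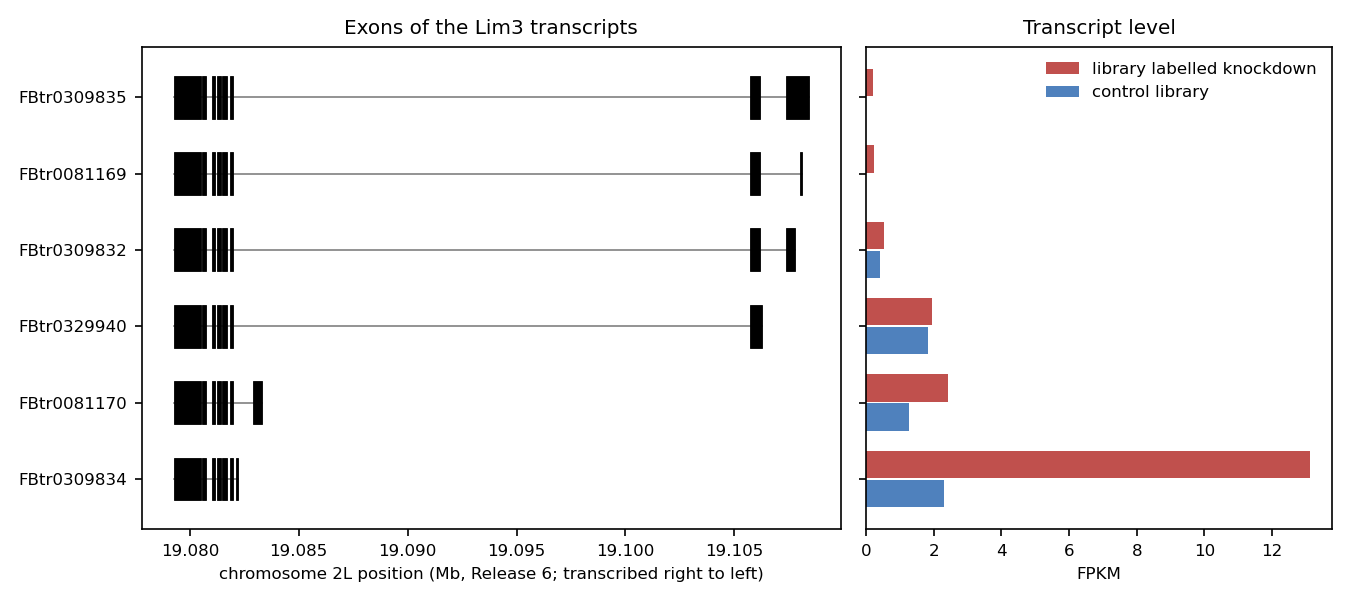
Exons of the 6 Lim3 transcripts by position on chromosome 2L (Mb, Release 6; left) and FPKM of each transcript in the library labelled knockdown and the control library (bars, 1 library each; right). The bar of FBtr0309834 reaches 13.1 FPKM in the library labelled knockdown against 2.30 in the control library, while FBtr0329940 is at 1.95 and 1.83.

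The other genes of the LIM-homeodomain and LIM cofactor list were closer between the libraries. Of the 9 measured genes, 7 lay above 0 and Lim3 was the only gene past the size rule. tup, an islet-class LIM-homeodomain gene of motor neurons, was at 8.84 FPKM in the library labelled knockdown and 6.20 in the control library (log2 0.45, 1.43-fold, 1.27 to 1.60). ap, which acts in interneurons and muscle, was at 7.08 and 5.81 FPKM (0.25), and Lim1 at 2.68 and 2.19 FPKM (0.20). CG32105, now named Lmx1a, was at 4.38 and 3.86 FPKM (0.15), Bx at 5.96 and 5.57 FPKM (0.08), and CG4328 at 3.20 and 3.15 FPKM (0.01). The cofactor genes Ssdp and Chi had log2 differences of -0.04 and -0.13, at 36.6 and 37.6 FPKM and at 66.5 and 72.6 FPKM. The list's median was 0.15 (-0.04 to 0.45), at percentile 87.8 of random lists.

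Across all 10576 tested genes the libraries were alike. The log2 values had a Pearson correlation of 0.971 across genes, which are not independent replicates. On the scale with 1 added to each FPKM, 94.2% of genes (9958) differed by less than 1.5-fold. That scale counts some genes of low FPKM as alike though their plain ratio is larger. By the size rule 108 genes were at least 2-fold higher and 145 at least 2-fold lower in the library labelled knockdown. Rescaling both libraries to an equal sum added 0.28 to the log2 difference of genes well above the pseudocount and turned the split to 146 higher and 100 lower, so the majority direction rests on the scale. The FPKM sum over genes was 1122636 in the library labelled knockdown and 1363810 in the control library. Ribosomal protein genes held 45.9% and 51.2% of these sums, so rescaling carries much of the ribosomal protein difference. Genes at 5 FPKM or more in both libraries had a median log2 ratio of -0.08 before rescaling, so adding 0.28 puts a typical gene above 0.

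**Figure D2:**
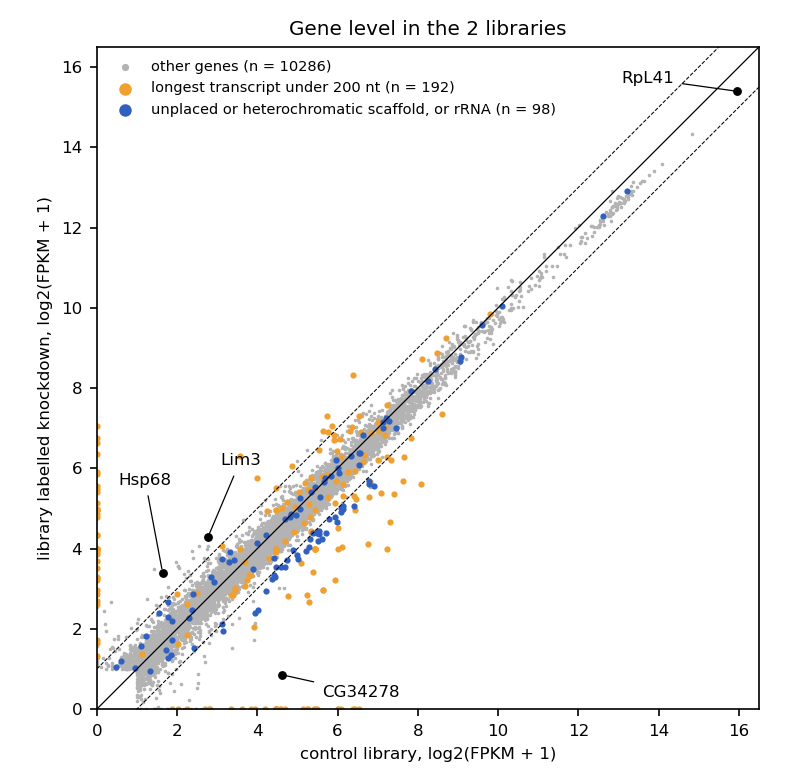
Gene level as log2(FPKM + 1) in the control library (x axis) and in the library labelled knockdown (y axis), 1 point per tested gene; the solid line marks equal values and the dashed lines a 2-fold difference. Genes under 200 nt (192) scatter far from the line and include many listed at 0 in 1 of the libraries, and a band of genes from unplaced scaffolds lies below it.

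Many genes past the size rule encode small RNAs. Of the 192 tested genes whose longest transcript is under 200 nt, 47 were at least 2-fold higher and 68 at least 2-fold lower in the library labelled knockdown, and 38 and 35 of these were listed at 0 in the other library. They comprised 28 higher and 35 lower of 114 small nucleolar and Cajal body RNAs, 9 higher and 22 lower of 41 genes of 5S ribosomal RNA, 5 higher and 7 lower of 17 spliceosomal RNAs and similar small nuclear RNAs, 2 higher and 1 lower of 5 microRNA precursors, and 3 higher and 3 lower of other kinds. The 12 highest and 12 lowest genes by the original naming rule were all under 200 nt. snRNA:U5:14B, a U5 spliceosomal RNA, was at 107 FPKM in the library labelled knockdown and listed at 0 in the control library, while snoRNA:Psi28S-1175a was listed at 0 and at 92.0 FPKM. Its near neighbour in the same host region, snoRNA:Psi28S-1175b, was at 59.4 FPKM and listed at 0. These RNAs are shorter than the 250 to 400 bp molecules kept for sequencing and exist as similar copies, so their FPKM is uncertain.

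Among genes of 200 nt or more outside unplaced scaffolds, a restriction chosen after the data were seen, 61 were at least 2-fold higher and 45 at least 2-fold lower, of 10286 tested. Rescaling to an equal sum gave 92 and 29, a pseudocount of 5 gave 9 and 8, and a pseudocount of 0.1 gave 124 and 107. A filter at 5 FPKM gave 31 and 17, and removal of the length trend 74 and 37. The largest difference among higher genes at 5 FPKM or more was at Hsp70Bb, a stress-inducible chaperone gene, at 5.35 and 0.281 FPKM (log2 2.31). The Hsp70 copies are nearly identical, and the 6 copies summed to 10.6 FPKM in the library labelled knockdown and 1.16 FPKM in the control library, a 9.13-fold ratio (6.96 to 12.1). Hsp68, a related chaperone gene on 3R from 19880113 to 19883032, was at 9.53 and 2.12 FPKM (1.76; 4.50-fold, 3.66 to 5.64). Cyp4p2, a cytochrome P450 gene, was at 11.7 and 2.90 FPKM (1.70; 4.02-fold, 3.29 to 4.99). Serine protease genes of the gut were also among the higher genes, with alphaTry at 10.8 and 3.05 FPKM (1.54) and Jon25Biii at 15.7 and 4.88 FPKM (3.21-fold, 2.54 to 4.10). With a pseudocount of 5, Hsp70Bb and alphaTry missed the size rule (0.97 each).

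The other higher genes under the added length criterion were CG34437 at 14.3 and 4.14 FPKM, CG16713 at 10.8 and 3.07 FPKM and CG32074 at 12.6 and 4.24 FPKM. SP, which encodes the sex peptide of the male accessory gland, was at 5.71 and 1.37 FPKM (4.16-fold, 1.90 to 12.9) on few fragments. The noncoding genes CR44410 and CR43956 were at 10.2 and 1.68 FPKM and at 10.4 and 3.13 FPKM. Both lie just over 200 nt, at 230 and 201 nt. With a pseudocount of 5, CG16713 (0.97), CG32074 (0.93), SP (0.75) and CR43956 (0.93) missed the size rule.

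CG34278 had the lowest log2 difference among the placed genes of 200 nt or more, at 0.809 FPKM in the library labelled knockdown and 23.4 FPKM in the control library (-3.76; 29.0-fold lower). It stood on about 9 and 170 fragments. Its longest transcript has 344 nt, shorter than those behind the fragment estimate, so these fragment numbers are less certain. CG13560 on 2R, from 19635083 to 19636000, was at 2.31 and 14.1 FPKM (-2.19; 6.10-fold lower, 4.50 to 8.55). CG17362 was at 1.86 and 9.41 FPKM (-1.86), CG12310 at 3.46 and 14.4 FPKM (-1.78) and CR42842 at 7.03 and 24.3 FPKM (-1.66). CG42815 was at 7.06 and 22.3 FPKM (-1.53), CG18367 at 1.27 and 5.53 FPKM (-1.52) and CG43134 at 1.48 and 5.34 FPKM (-1.35). Victoria, now named TotE and a member of the Turandot family of stress-responsive secreted peptides, was at 3.80 and 10.7 FPKM (-1.28; 2.81-fold lower, 2.07 to 3.87). The noncoding genes CR34335 and CR44886 were at 45.4 and 110.4 FPKM and at 3.35 and 9.30 FPKM, and CR45340 was listed at 0 and at 5.05 FPKM. The size rule was missed by CG18367 (-0.75), CG43134 (-0.67), Victoria (-0.83) and CR44886 (-0.78) with a pseudocount of 5, and by CR34335 (-0.98) and CR44886 (-0.97) after rescaling.

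Most genes on the unplaced scaffold U were lower in the library labelled knockdown. Of 43 tested genes of 200 nt or more on it, 40 with CR symbols, 39 lay below 0 and 30 were at least 2-fold lower, with a median of -1.09 (quartiles -1.20 and -0.97). The number at least 2-fold lower was 8 after rescaling (median -0.81), 15 with a pseudocount of 5 and 20 with the length trend removed, and 39 lay below 0 in each case. The 3 genes there without a CR symbol had a median of 0.25. The lowest named by the rule were CR40962 at 4.58 and 15.1 FPKM (-1.53) and CR40728 at 17.7 and 47.7 FPKM (-1.38), and CR40677 on the X heterochromatin scaffold, a 2S ribosomal RNA pseudogene by its current name, was at 4.22 and 14.4 FPKM (-1.56). All 6 genes of 200 nt or more whose current name is that of a nuclear ribosomal RNA or its pseudogene were below 0, with a median of -1.17, and their sums were 89.1 FPKM in the library labelled knockdown and 213 FPKM in the control library. On the heterochromatic scaffolds of chromosomes 2 and 3, by contrast, the median of 43 genes was 0.05. Some genes on these scaffolds may be copies that share sequence, which was not examined, so the values of single genes are uncertain.

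Of the 32 gene lists, 31 had enough measured genes for a value, and 11 lay outside the range of random lists, 8 above and 3 below. Chance would give about 1.55 if list members varied independently. Members of a list can move together, so the 11 cannot be read as an excess over chance. Medians below 0 depended on the scale. After rescaling, those of the ribosomal protein and cell cycle lists stayed below 0 and those of all other lists were above 0. The percentiles kept their side of the limits for all 31 lists under rescaling.

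**Figure D3:**
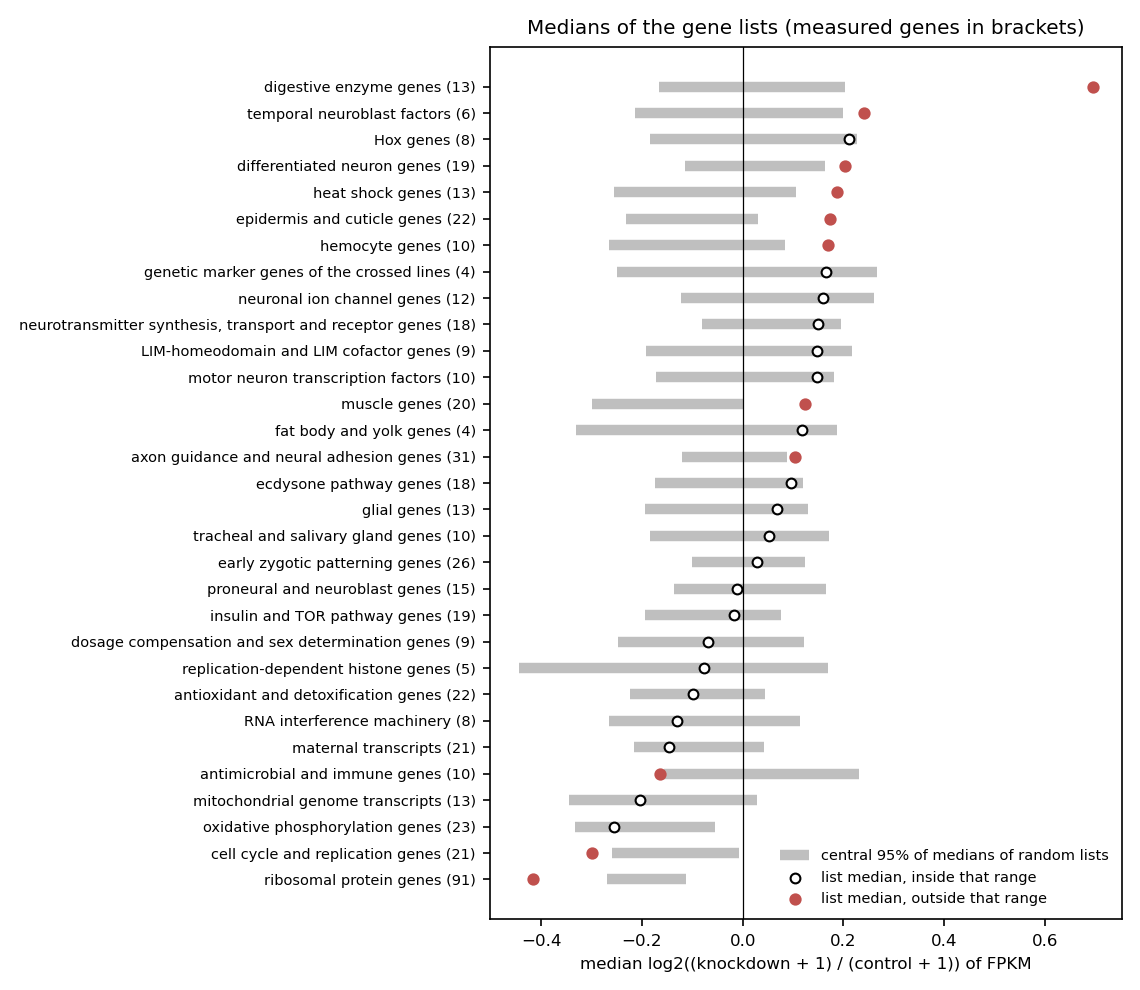
Median log2 difference of each list's measured genes (points; number of genes in brackets) and the central 95% of medians of 10000 expression-matched random lists (grey bars), in log2 units. Digestive enzyme genes have the highest median (0.70) and ribosomal protein genes the lowest (-0.42); rescaling turns the sign of all medians below 0 except those of the ribosomal protein and cell cycle lists.

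Lists of neurons and their precursors were divided. Differentiated neuron genes had a median of 0.20 (-0.09 to 0.40, percentile 99.4), with 12 of 19 genes above 0 and none past the size rule. nrv3, a sodium pump subunit of neurons, was at 10.1 and 5.82 FPKM (0.70), cpx, a regulator of synaptic vesicle release, at 11.8 and 7.05 FPKM (0.67), and Syt1, the calcium sensor of release, at 5.23 and 3.57 FPKM (0.44), whereas elav, a pan-neuronal RNA-binding protein gene, was at 15.2 and 16.3 FPKM (-0.09) and Syx1A at 7.41 and 11.2 FPKM (-0.54). The mean of the neuron list was 0.17, at percentile 88.0, and its median with a pseudocount of 5 was 0.09, at percentile 96.9, both inside the range. Temporal neuroblast factors had a median of 0.24 (-0.05 to 0.43, percentile 99.1, but 94.8 with the mean and 96.4 with the length trend removed), with 5 of 6 genes above 0, such as nub at 12.5 and 9.01 FPKM (0.43) and cas at 11.1 and 8.22 FPKM (0.39). Axon guidance and neural adhesion genes had a median of 0.10 (percentile 98.6), with 26 of 31 above 0, but matching the random lists on length as well put the list at percentile 95.5, the mean at 88.3 and removal of the length trend at 78.8. Proneural and neuroblast genes had a median of -0.01, or 0.20 after rescaling, at percentile 31.2. The motor neuron transcription factors, the list nearest to the known role of Lim3, had a median of 0.15 (-0.01 to 0.35) at percentile 93.5, with 8 of 10 above 0; exex was at 7.23 and 5.94 FPKM (0.25) and eve at 14.3 and 15.7 FPKM (-0.13). Neurotransmitter genes were at 0.15 (percentile 88.0), neuronal ion channel genes at 0.16 (percentile 79.5) and glial genes at 0.07 (percentile 86.8), all inside the range.

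Lists of other differentiated tissues lay high among random lists. Muscle genes had a median of 0.12 (percentile 100), with 18 of 20 above 0, among them Prm, which encodes paramyosin, at 158 and 128 FPKM (0.30) and wupA, a troponin I gene, at 621 and 506 FPKM (0.29). Epidermis and cuticle genes had a median of 0.17 (percentile 100), with 20 of 22 above 0, such as the cuticle gene TwdlM at 752 and 574 FPKM (0.39) and neo at 82.4 and 56.7 FPKM (0.53). Hemocyte genes had a median of 0.17 (percentile 99.8, or 97.3 with the length trend removed), with 9 of 10 above 0. The collagen IV genes vkg and Cg25C were at 53.2 and 41.5 FPKM and at 90.1 and 70.4 FPKM (0.35 each). These differences were small, and none of the genes in these 3 lists passed the size rule. Digestive enzyme genes had the highest median, 0.70 (0.01 to 1.22; percentile 100), and 5 of 13 passed the size rule. With a pseudocount of 5 the median was 0.23 (percentile 99.99) and 1 gene passed, and with no filter the median was 0.46 (percentile 100). Beside alphaTry and Jon25Biii these were epsilonTry at 2.37 and 0.441 FPKM (1.22), Jon25Bi at 2.48 and 0.669 FPKM (1.06) and Jon65Aiv at 25.2 and 11.7 FPKM (1.05), while Jon65Aiii was at 44.9 and 41.4 FPKM (0.11). Tracheal and salivary gland genes (median 0.05, percentile 70.6) and the 4 measured fat body and yolk genes (0.12, percentile 92.1) were inside the range.

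Ribosomal protein genes had the lowest median of all lists in the library labelled knockdown. Of 91 measured genes 90 lay below 0, with a median of -0.42 (-0.45 to -0.40; percentile 0), and none passed the size rule; the median was -0.15 after rescaling. RpL41 was at 43092 and 63983 FPKM (-0.57), and RpS5b, a germline-enriched paralog, at 545 and 941 FPKM (-0.79). The list made up 45.9% of the FPKM sum in the library labelled knockdown and 51.2% in the control library. Cell cycle and replication genes had a median of -0.30 (-0.37 to -0.16; percentile 0.565), or -0.023 after rescaling, with 19 of 21 below 0; with the mean the percentile was 2.72, inside the range. The mitotic kinase genes ial, now aurB, and cdc2, now Cdk1, were at 62.7 and 91.9 FPKM (-0.54) and at 172 and 232 FPKM (-0.43), and the replication clamp gene PCNA was at 238 and 315 FPKM (-0.40). All 23 nuclear oxidative phosphorylation genes lay below 0, with a median of -0.26, but at percentile 22.9 they did not stand apart from genes of like expression, and the median was 0.023 after rescaling. The 13 measured transcripts of the mitochondrial genome had a median of -0.20 (0.08 after rescaling) at percentile 32.8.

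The difference between the libraries varied with transcript length. Among 8055 genes at 5 FPKM or more in both libraries and of 200 nt or more, Spearman's correlation of the log2 ratio with transcript length across genes was 0.267, and the median ratio went from -0.17 in the bin of shortest transcripts to 0.04 in that of the longest. Matched on length as well as expression, ribosomal protein genes (percentile 0), cell cycle genes (0), muscle genes (99.98), epidermis and cuticle genes (100) and differentiated neuron genes (99.6) remained outside the range.

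**Figure D4:**
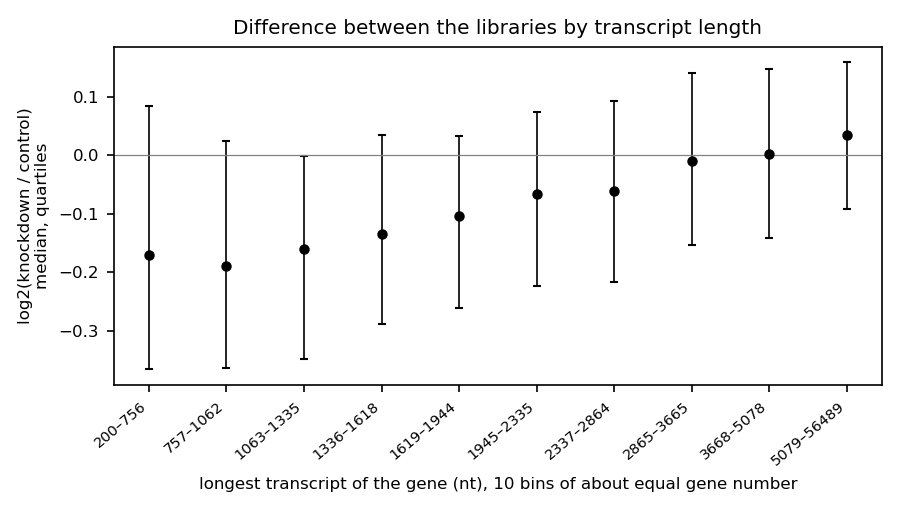
Median log2 ratio of FPKM in the library labelled knockdown over the control library (points) with quartiles (bars), in 10 bins of the length in nt of a gene's longest transcript (x axis). The medians go from -0.17 in the shortest bin and -0.19 in the next to 0.04 in the longest.

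Lists that follow the age of a pool, where they had a value, were inside the range of random lists before any alternative was applied. Maternal transcripts had a median of -0.15 (0.13 after rescaling) at percentile 17.7, with 12 of 21 below 0. The percentile was 4.3 with random lists matched on length too, 7.8 with the length trend removed and 58.9 with the mean. bcd, which encodes the anterior determinant, was at 24.5 and 36.2 FPKM (-0.54), and osk, which encodes the organizer of the germ plasm, at 34.8 and 27.0 FPKM (0.35). Early zygotic patterning genes had a median of 0.03 at percentile 59.5, with prd at 4.90 and 6.64 FPKM (-0.37) and zen at 6.61 and 4.20 FPKM (0.55). All 8 Hox genes lay above 0, with a median of 0.21 at percentile 96.4, inside the range. It was 97.2 with random lists matched on length too, 91.8 with the length trend removed and 89.2 with the mean. Ecdysone pathway genes had a median of 0.10 at percentile 95.2; this list went outside the range with a pseudocount of 0.1 (97.7) and with a filter at 5 FPKM (98.8). Of 12 chorion and vitelline membrane genes only Cp18 was measured, at 0.526 and 1.28 FPKM, so the list has no value. The histone list had 5 measured genes, of which His3.3A, His3.3B, His4r and His2Av are not replication-dependent, with a median of -0.08 (0.20 after rescaling) at percentile 71.9.

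Heat shock genes had a median of 0.19 (percentile 99.7) and a mean of 0.52, and 3 of 13, Hsp70Bb, Hsp68 and Hsp70Bc, were at least 2-fold higher in the library labelled knockdown, but only Hsp68 was with a pseudocount of 5. The small heat shock genes Hsp22 and Hsp26 were at 14.2 and 12.6 FPKM and at 290 and 255 FPKM, and Hsp67Bb, which was lowest in the list, at 38.0 and 72.7 FPKM (-0.92). Antimicrobial and immune genes had a median of -0.16 (0.06 after rescaling) at percentile 2.11, with 7 of 10 below 0, such as Mtk, an antifungal peptide gene, at 5.08 and 7.21 FPKM (-0.43). That position was lost when random lists were matched on length too (percentile 13.9), with the mean (12.4), with no filter (6.31) and with a filter at 5 FPKM (20.9). The remaining lists were inside the range. They were antioxidant and detoxification genes (median -0.10, or 0.18 after rescaling; percentile 46.6), insulin and TOR pathway genes (-0.02, or 0.25; percentile 72.7), RNA interference machinery (-0.13, or 0.12; percentile 26.6) and dosage compensation and sex determination genes (-0.07, or 0.19; percentile 46.6).

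The marker genes of the crossed lines had a median of 0.17 at percentile 88.0. y, the body pigment gene yellow, was at 12.7 FPKM in the library labelled knockdown and 5.33 FPKM in the control library (1.11, or 0.77 with a pseudocount of 5; 2.37-fold, 2.05 to 2.75), although the labels name a wild-type copy of it only for the control transgene. v, which encodes an enzyme of the brown eye pigment pathway, was at 11.7 and 9.90 FPKM (0.22; 1.18-fold, 1.02 to 1.37). w was at 13.5 and 12.5 FPKM (0.11) and Ser at 7.89 and 8.54 FPKM (-0.10). en, the host gene of the driver's enhancer, was at 8.20 and 8.86 FPKM (-0.10; 0.15 after rescaling).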

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

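The restriction to genes of 200 nt or more and the removal of the length trend were chosen after seeing the data; the other alternatives were planned. Of the 52 named genes past the size rule, Lim3 included, 11 missed it with a pseudocount of 5 and 2 after rescaling. None missed it with a pseudocount of 0.1, centring or the length trend removed, and none turned its sign under these alternatives. The 52 include 12 higher and 12 lower RNAs under 200 nt listed at 0 in the other library. Their levels are too high for these pseudocounts to bring them under the size rule, so they add nothing to this check. All genes that missed it were of 200 nt or more. Of the 11 lists outside the range of random lists, 11 kept their side under centring, rescaling, a pseudocount of 0.1 and the restriction to 200 nt or more, 10 with a pseudocount of 5, no filter or a filter at 5 FPKM, 9 with length-matched random lists, 8 with the length trend removed and 6 with means. Causes of the moves were not tested, except that centring adds a constant of 0.076 by construction, that rescaling adds 0.28 to genes far above the pseudocount and other amounts to low genes, and that a larger pseudocount pulls low genes toward 0.

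The counts of 108 higher and 145 lower genes became 177 and 210 with a pseudocount of 0.1, 52 and 90 with a pseudocount of 5, and 61 and 77 at 200 nt or more. The Lim3 difference of 1.51 became 1.12 with a pseudocount of 5 and 1.73 after rescaling. It was above 1 under all alternatives run for it. With means, the percentiles were 94.8 for temporal neuroblast factors, 88.0 for differentiated neuron genes, 88.3 for axon guidance, 2.72 for cell cycle and 12.4 for immune genes. With length-matched random lists they were 95.5 for axon guidance and 13.9 for immune genes. With the length trend removed they were 96.4 for temporal neuroblast factors, 78.8 for axon guidance and 97.3 for hemocyte genes, and the medians were -0.28 for ribosomal protein and 0.045 for histone genes. The neuron percentile was 96.9 with a pseudocount of 5, where the median was 0.09. The ecdysone list moved outside the range, to 97.7 with a pseudocount of 0.1 and 98.8 with the filter at 5 FPKM, and the immune list inside it, to 6.31 with no filter and 20.9 with that filter. The ion channel median was 0.22 with a pseudocount of 0.1, and the histone median 0 with no filter. Among lists outside the range, moves of a median by over 1.5 times without a changed call included those of digestive genes, to 0.23 with a pseudocount of 5 and 0.46 with no filter, of heat shock genes, to 0.46 after rescaling and 0.32 with the length trend removed, of neuron genes, to 0.31 with a filter at 5 FPKM, of muscle genes, to 0.20 with centring, and of immune genes, to -0.094 with a pseudocount of 5, -0.088 with centring and -0.11 with the length trend removed.

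After rescaling, the medians were 0.37 for motor neuron factors, 0.20 for proneural, 0.50 for temporal, 0.44 for neuron, 0.34 for axon guidance, 0.35 for neurotransmitter, 0.33 for ion channel, 0.34 for glial, 0.40 for muscle, 0.45 for epidermis, 0.44 for hemocyte, 0.39 for fat body, 0.28 for early zygotic, 0.43 for Hox, 0.27 for ecdysone, 0.20 for histone, 0.18 for antioxidant and 0.25 for insulin genes. They were 0.023 for oxidative phosphorylation, -0.023 for cell cycle and -0.15 for ribosomal protein genes. With centring they were 0.18 for axon guidance, 0.24 for ion channel, 0.19 for fat body, 0.17 for ecdysone, -0.34 for ribosomal protein and -0.00015 for histone genes.

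The planned comparison of the authors' confidence intervals was not run, since the files give none. The chorion list gave no value. No paired analysis was possible because each group has 1 library. Depth limits the genes near 1 FPKM, where 1 fragment of a 1000 nt transcript is worth about 0.0297 FPKM in the library labelled knockdown and 0.0475 FPKM in the control library.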

Other observations

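The tests on chromosome 4, neighbouring genes, the Lim3 transcripts, v, scaffold U and the age of the pool were chosen after the results were seen, as was the use of length-matched random lists to weigh the length trend; the gene lists and those random lists themselves were planned.

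Genes of chromosome 4 lay higher in the library labelled knockdown as a set. The 90 tested genes of 200 nt or more had a median log2 difference of 0.14 (0.11 to 0.18), with 69 above 0, while the central 95% of random sets matched on expression and length ran from -0.04 to 0.07 (percentile 100). The medians of the large arms were between -0.06 on X and -0.03 on 3L, at percentiles 0.09 and 99.98 of such sets.

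Lower genes included 4 pairs of direct neighbours in the Release 6 gene order, where 10000 random sets of 43 genes matched on expression gave 0.24 on average and 4 at most. The pairs were CG13560 with CG11300, CG17362 with CG9040, CG32188 with CG32189, and ng4, a gene of the salivary glands, with CR44886. Higher genes included 3 pairs, alphaTry with epsilonTry, yip7 with Jon65Aiv and Hsp70Bb with Hsp70Bc, where random sets of 59 genes gave 0.43 on average and 4 at most, and 73 of 10000 gave as many or more. The random sets were not matched on gene family or shared sequence. Similar neighbours, such as the Hsp70 copies, can share fragments, so these counts do not show an effect of position.

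Lim3 was 3.17-fold higher in the library labelled knockdown. An equal increase of all transcripts is not what the estimates show. Transcripts with a distal first exon, summed, were 1.29-fold higher (1.05 to 1.61) and the shortest transcript, nearly all of it shared exons, 5.71-fold (4.70 to 7.04). All these values rest on the software's division of shared-exon fragments, and error in it is in neither interval. However, 2 distal transcripts of low level were also higher, FBtr0081169 at 0.244 and 0.00158 FPKM and FBtr0309835 at 0.200 FPKM and listed at 0. A candidate explanation is that fragments of the RNA interference transgene itself were counted as Lim3. It requires that the construct holds a long enough stretch of Lim3 sequence, which was not examined. The lower summed ratio goes with this explanation. Those 2 transcripts do not decide it, because shared-exon fragments were divided among them too. More native transcript from the proximal start cannot be told apart from it without the reads. Exchanged labels also stay open, as does whether native Lim3 was reduced. v, which such constructs usually carry as a marker, differed by 0.22 in log2, inside the -0.54 to 0.57 of genes at a like level, and the 2.37-fold higher y would go with an exchange only if the RNA interference insertion lacked the y copy that the labels name for the control.

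Lists of differentiated neurons, muscle and epidermis lay high and those of ribosomal proteins and the cell cycle low among random lists, though with means the neuron (percentile 88.0) and cell cycle (2.72) lists were inside the range. The tables argue against transcript length as the whole cause for these lists, because with random lists matched on length the percentiles were 99.6 for neuron, 99.98 for muscle, 100 for epidermis, 0 for ribosomal protein and 0 for cell cycle genes. Axon guidance genes moved to 95.5, so for this list the length trend cannot be told apart from a shift of its own. The matching used 10 bins of expression and 10 of the longest transcript's length, so differences within a bin remain. Within ribosomal protein genes the log2 ratio still rose with length (Spearman's correlation 0.33). With the length trend removed, the neuron, muscle, epidermis, ribosomal protein and cell cycle lists also stayed outside the range. A pool that was older on average may give the same pattern of high and low lists. The digestive enzyme (percentile 100), hemocyte (99.8), heat shock (99.7), temporal neuroblast (99.1) and immune (2.11) lists also lay outside the range. Whether an older pool would move them this way was not tested. The early zygotic list, taken to be low in an older pool, stood at percentile 59.5, but whether its genes do fall by 16 h was not tested. The maternal list stood at percentile 17.7, at 4.3 with random lists matched on length too and at 58.9 with its mean. These lists neither exclude nor require an older pool. An effect of the Lim3 construct stays open and untested, since each genotype is a single pool.

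Genes of the unplaced scaffold U were mostly lower in the library labelled knockdown. Chance division of fragments among near-identical copies would send about as many up as down, and 39 of 43 were lower, among them 38 of the 40 with CR symbols. Less ribosomal RNA left after poly(A) selection stays open, because only 2 genes of 200 nt or more named as ribosomal RNA pseudogenes lie outside this scaffold, with a median of -1.41, and that the unnamed genes of the scaffold hold ribosomal sequence was not tested. Of the 41 genes of 5S ribosomal RNA, all under 200 nt and uncertain, 28 were lower, with a median of -1.44 and quartiles of -4.47 and 0.48. The mitochondrial ribosomal RNA gene mt:lrRNA was at 4992 FPKM in the library labelled knockdown and 6256 FPKM in the control library (-0.33). No biological explanation was tested.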
